A study of Brachypodium distachyon with 18 samples.

How the data were processed

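RNA sequencing was done on total RNA from whole 2-week-old seedlings, extracted with a silica column kit, with libraries and sequencing by a commercial provider, per the labels' protocols. FastQC, kallisto and sleuth are named in the submitters' processing notes, without versions. The transcript reference and genome build are not given in the sources used here. Kallisto assigns reads to transcripts without alignment to a genome and shares reads that fit several transcripts, so near-identical copies of a gene may exchange counts. A read from a sequence variant that departs from the reference is assigned less readily, which can lower the count of a locus that differs from the reference.

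Each sample came with 2 tables of 52972 transcripts. The estimated count per transcript is the authors' deposited value, as the column names of the files give it, and it was neither normalized nor whole. The TPM value per transcript, a length-corrected share of the library, is also the authors' deposited value. Both tables of a sample agreed within 0.494 counts at every transcript, and the first was used. The authors' deposited comparison tables, 4 in number, hold a p-value and q-value per transcript and an effect on the natural log scale, as computed by the authors with the sleuth columns per the file headers. They also hold 24 columns of per-sample values under names that match no sample label, and these were not used in any step.

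Estimated counts were summed over the transcripts of a locus by removing the transcript suffix of the identifier, giving 34310 loci, of which 26300 had 1 transcript, and were rounded to whole numbers. CPM values are these counts scaled to a library total of 1000000. The reference table of names had 31335 genes and matched 0 of the 34310 locus identifiers, so no gene is named. For the same reason the 37 gene lists fixed in advance, which select genes by their description, could not be filled, and their set tests were not run. Named loci follow a rule fixed before the data were examined: called in both lines in the same direction, a mean log2 CPM of at least 1, every line library beyond every wild-type library, and the largest mean log2 fold change. The part of the rule that asks for a description could not be applied. Because identifiers carry no name, only 2 loci that rose and 2 that fell are printed: the first on each set's list in each direction and, where both sets had the same first locus, the next on the amiR list. Other parts of the rule, which named loci per line, per list or across sets, are not printed.

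Differential abundance was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion, TMM scaling, the default filter on low counts by group, and Benjamini-Hochberg adjustment at 0.05. The 9 libraries of a set were fitted together, with contrasts for line 1, line 2 and the mean of both lines against wild type. All 18 libraries in 6 groups were fitted together for the difference between the transgene effects and for the difference between the wild types. Standard deviations are over 3 libraries. Where a group was at 0, the fold is a lower bound against 3 counts over the total depth of that group. Depths of 18358136 to 28980649 counts put this floor between 0.0355 and 0.0528 CPM, and floors cover counting error only.

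The procedure was tested on simulated data drawn from the real means and library sizes with 200 changed loci. The changed loci all had a mean of at least 1 CPM, so recovery at lower means was not tested. In the amiR design, with 24160 loci tested, the contrast for line 1 recovered 10% of 2-fold and 65% of 4-fold changes, and the mean of both lines recovered 22% and 79%. In the RGS design, with 25280 loci tested, line 1 recovered 29% and 88%, and the mean of both lines 52% and 96%. Between 4 and 9 unchanged loci were called. Changes of 2-fold are thus often missed, most of all in the amiR set.

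Overlaps between lines that share controls were set against 20 simulations of unchanged lines. In these all 9 libraries of a set, controls included, were drawn around a common mean, each locus on its own. No pair of replicates agreed within counting noise, so that each library was counted. Alternatives fixed before the data were examined were DESeq2 1.42.0, relative log expression and upper quartile scaling, no filter, a filter at a mean of 50 counts, fits on the compared groups only or on all 18 libraries, a replicate block, transcripts in place of loci, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), an adjusted p of 0.01, a log2 fold change of at least 1, the other table of each sample, and each library left out in turn. Alternatives chosen after seeing the data used the third amiR-set wild-type library as the only control, the pairs of groups that match the authors' tables, and the overlap without on/off loci. The check of the tables against the labels took means of log counts scaled by median ratios, over transcripts with a mean above 50 scaled counts on the log scale. Neighbouring loci were taken from the order of locus names, in which the digit after the prefix is the chromosome.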

Results

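Messenger RNA abundance was measured in whole seedlings of the grass Brachypodium distachyon, collected at 2 weeks of age after growth at 25 degrees Celsius. Plants carried either of a pair of transgenes that act on the heterotrimeric G-protein, a membrane-associated signalling complex whose alpha subunit binds GTP. The first transgene was an artificial microRNA (amiR) directed at the Brachypodium alpha subunit. The second was labelled SiRGS-OE, where RGS stands for a regulator of G-protein signalling, a protein that speeds up GTP hydrolysis by the alpha subunit. There were 2 independent lines per transgene, and each transgene had its own wild-type control, so that 18 libraries fell into 6 groups of 3. The amiR set held amiR line 1, amiR line 2 and their wild type, and the RGS set held RGS line 1, RGS line 2 and theirs. Total estimated counts ran from 18358136 to 28980649 per library. The group means were 20661419 ± 592460 counts for the amiR-set wild type, 22710967 ± 3384267 for amiR line 1 and 18937049 ± 570818 for amiR line 2 (SD, n = 3). They were 27766320 ± 159605 counts for the RGS-set wild type, 26030605 ± 3636670 for RGS line 1 and 28187934 ± 1216431 for RGS line 2 (SD, n = 3). Counts were given for 34310 loci after summing transcripts. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these libraries, which may be partly technical. The targeted alpha subunit locus and the introduced transcript were not analysed here, because the sources used here do not pair locus identifiers with gene names. Group names below are those of the sample labels. The authors' deposited tables name 3 of the 6 groups otherwise, as shown at the end of these results, so all comparisons and counts rest on the sample labels.

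Libraries separated first by set. Along the first principal component, which held 42.8% of the variance, the 9 amiR-set libraries lay below 0 and the 9 RGS-set libraries above it. The sets also differed in fragment length as the quantification estimated it: transcript length exceeded effective length by a median of 226.1 to 242.5 nt in the amiR set and 276.6 to 286.8 nt in the RGS set. Set and library batch therefore cannot be told apart, and the comparisons with wild type were made within a set. Within the amiR-set wild type, the third library stood apart from the first and second. Across loci, its log2 values correlated with theirs at r = 0.820 and 0.834, against 0.984 between those 2 libraries. Its closest library was the first of amiR line 1 (r = 0.924). In the other 5 groups the mean correlation between replicates ran from 0.953 to 0.991. Loci are not independent replicates, and these correlations describe libraries only.

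**Figure D1:**
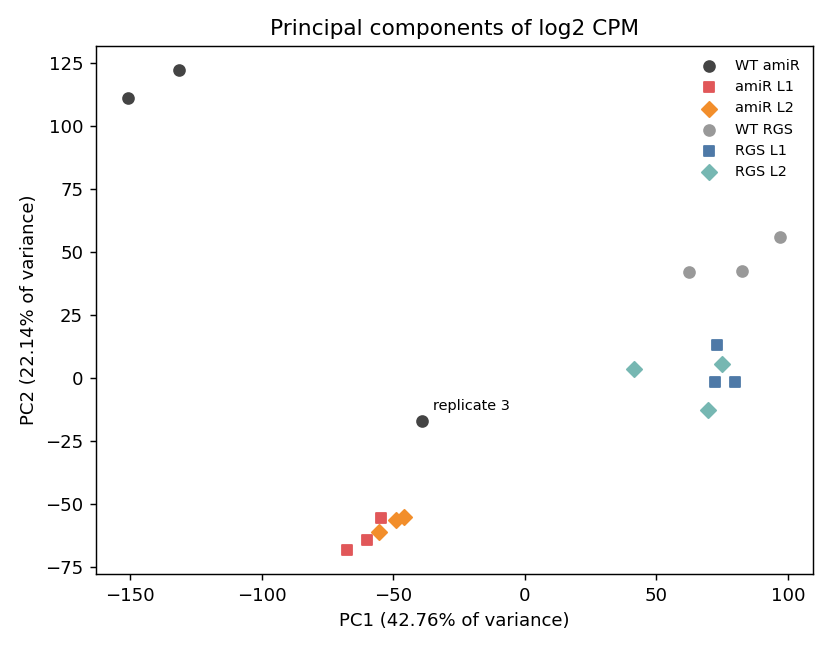
Scores of the 18 libraries on the first (x axis, 42.76% of the variance) and second (y axis, 22.14%) principal components of log2 CPM (counts scaled to a library total of 1000000), 1 point per library, coloured by labelled group. The third library of the amiR-set wild type lies at -38.9 on the first component, and the first and second lie at -131.2 and -150.6.

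The first comparison asked which transcripts differed when the alpha subunit was targeted by the artificial microRNA. In both amiR lines, 1337 loci differed from wild type in the same direction, of which 532 were higher and 805 lower, and 0 loci were called in opposite directions. The locus Bradi2g09915 rose from 0 counts in every wild-type library to 65.5 ± 19.9 CPM (counts scaled to a library total of 1000000) in line 1 and 50.2 ± 5.43 in line 2 (SD, n = 3). This is at least 1354-fold and 1038-fold higher, against a floor of 3 counts over the group (edgeR quasi-likelihood test, adjusted p = 0.000195 and 0.000186). It was not particular to the amiR lines: Bradi2g09915 was also at 0 counts in the RGS-set wild type and rose to 10.4 ± 3.31 and 6.94 ± 1.61 CPM in RGS lines 1 and 2 (SD, n = 3; edgeR, adjusted p = 2.28e-05 and 3.00e-05). The locus Bradi1g50760 stood at 161 ± 7.46 CPM in wild type (SD, n = 3) and fell to 0 counts in every library of both lines, at least 3657-fold and 3050-fold lower (edgeR, adjusted p = 0.000282 and 0.000251). In the RGS set Bradi1g50760 fell too, from 40.9 ± 12.95 CPM in the wild type (SD, n = 3) to a total of 1 count in RGS line 1 and 0 in RGS line 2 (edgeR, adjusted p = 1.98e-05 and 1.71e-05). Likewise Bradi3g48790 fell from 159 ± 97.1 CPM (SD, n = 3), with single libraries between 67.7 and 261 CPM, to 0 counts in both lines, at least 3610-fold and 3010-fold lower (edgeR, adjusted p = 0.0120 and 0.0130). These loci were taken by a rule of size fixed in advance. They are examples from 423 higher and 650 lower loci that were called in both lines, with every line library beyond every wild-type library.

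Line 1 alone had 2260 called loci (971 higher, 1289 lower) and line 2 had 1872 (770 higher, 1102 lower) of 24474 tested. The mean of both lines differed from wild type at 3793 loci, 15.5% of those tested, of which 1391 were higher and 2402 lower. The predominance of lower loci turned with the processing. With limma on log2(TPM + 1) and log2(TPM + 0.1), the mean of both lines had 2171 and 2048 higher and 1652 and 1587 lower loci. The same tests gave 1210 and 1116 higher against 1071 and 1054 lower in line 1, and 1182 and 1029 against 813 and 772 in line 2. For both lines they gave 726 and 664 higher against 631 and 593 lower. In the edgeR test, line 1 without its first library had 697 higher and 595 lower. Line 1 was near even without its second (216 and 214) or the third (222 and 217), or without the first wild-type library (486 and 483). In the edgeR test of the mean, 757 higher and 1316 lower loci changed by a log2 fold change of at least 1. Called loci were spread over all 5 chromosomes as the locus names give them, from 14.3% of tested loci on chromosome 2 to 17.5% on chromosome 4. Lines 1 and 2 differed from each other at 16 loci (edgeR quasi-likelihood test; 1326 at an unadjusted p below 0.05). The wild-type library that stood apart enters the spread used in this test, so differences between the lines may be missed. The common dispersion was 0.0974, against 0.0612 in the RGS set. Log2 fold changes of the lines correlated at Pearson's r = 0.873 and Spearman's rho = 0.840 across loci, and 84.9% of loci had the same sign in both lines. Simulated unchanged lines, with controls that were simulated too, gave r = 0.504 on average and a covariance of 0.0984, against an observed covariance of 0.984. The simulated controls lack the split between the real wild-type libraries, so the simulation may understate what shared controls give alone. In 20 simulations no locus was called in both simulated lines. The simulations held no changed locus, so few calls were to be had in either line and this count does not test the overlap. Independent lists of these sizes would share 30.5 higher and 58.0 lower loci. The controls were not split, since a part would have held fewer than 2 libraries, and part of the excess may come from the shared controls.

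The amiR counts moved with single libraries, most of all the wild-type library that stood apart. Without it, the edgeR test called 13105 loci in line 1, 12503 in line 2, 13823 in their mean and 10837 in both lines. With that library as the only control, an alternative chosen after seeing the data, the counts were 3878, 3974, 4228 and 2696. The mean of both lines then had 6899 higher and 6924 lower loci without that library, and 2127 and 2101 with it alone. Higher loci outnumbered lower ones in the lines and their overlap. Without it the balances were 6664 and 6441 in line 1, 6269 and 6234 in line 2 and 5445 and 5392 in both. With it alone they were 2062 and 1816, 2071 and 1903, and 1413 and 1283. Of the 3793 loci called in the mean of both lines, 1558 were called in the same direction against that library alone and 3784 were called without it. Leaving out the first or second wild-type library lowered the count in the mean of both lines to 1572 and 1193. It fell to 1692 and 1696 without the second or the third library of line 1, and to 1803, 1699 and 1631 without the first, the second or the third of line 2. Without any 1 library other than that wild-type library, 430 to 1292 loci were called in line 1, 398 to 1241 in line 2 and 351 to 735 in both.

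**Figure D2:**
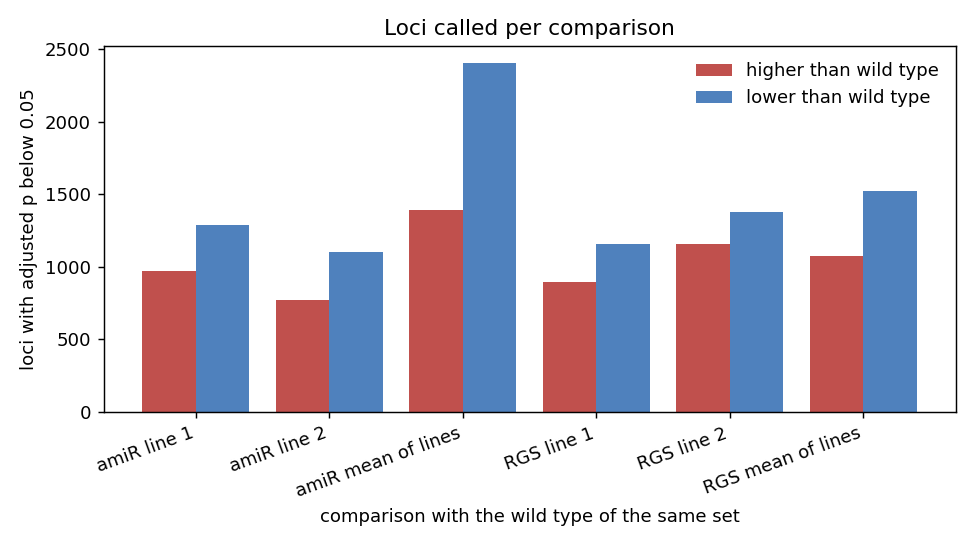
Number of loci with an adjusted p below 0.05 in each comparison with the wild type of the same set (x axis), as bars for loci higher (red) and lower (blue) than wild type. Lower loci outnumber higher ones in these edgeR tests, as in the mean of both amiR lines with 1391 and 2402, but limma on log2(TPM + 1) turned that balance to 2171 higher and 1652 lower.

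The second comparison asked which transcripts differed when the RGS transgene was present. Both RGS lines differed from wild type in the same direction at 1342 loci, of which 639 were higher and 703 lower, while 4 loci were called in opposite directions. The locus Bradi4g12025 rose from 0 counts in the wild type to 71.7 ± 39.0 CPM in line 1 and 72.7 ± 35.0 in line 2 (SD, n = 3), at least 1990-fold and 2018-fold higher (edgeR, adjusted p = 0.000443 and 0.000405). Bradi4g12025 was also present in libraries not labelled with the RGS transgene, at 39.5 ± 9.40 and 20.1 ± 3.22 CPM in amiR lines 1 and 2 and 18.7 ± 16.25 in the amiR-set wild type (SD, n = 3). The libraries of that wild type ran from 0 to 29.1 CPM, and the mean of both amiR lines did not pass the test (edgeR, adjusted p = 0.779). The locus Bradi3g48790, which had fallen in the amiR lines, fell here as well. It stood at 323 ± 62.4 CPM in the wild type (SD, n = 3) and at 0 counts in every library of both RGS lines, at least 8418-fold and 9116-fold lower (edgeR, adjusted p = 1.45e-05 and 1.37e-05). Such loci came from 430 higher and 419 lower ones that were called in both lines with every line library beyond every wild-type library.

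RGS line 1 had 2052 called loci (897 higher, 1155 lower) and RGS line 2 had 2537 (1157 higher, 1380 lower) of 25627 tested. In the mean of both lines 2598 loci were called, 10.1% of those tested, with 1075 higher and 1523 lower. In line 1 the balance turned to 994 higher and 961 lower with limma on log2(TPM + 0.1), and to 827 and 756 with transcripts in place of loci. The balance for both lines was near even and turned as well, to 643 higher and 477 lower with transcripts and 667 and 663 with limma on log2(TPM + 0.1). It also turned with a mean of at least 50 counts (408 and 398) and an adjusted p of 0.01 (406 and 379). Leaving out 1 library turned it without the second wild-type library (508 and 487) and without the first or the third of line 1 (507 and 497, 515 and 507). Of the loci called in the mean, 702 higher and 1019 lower loci changed by a log2 fold change of at least 1. Called loci made up 8.53% of tested loci on chromosome 1, 12.4% on chromosome 4 and 12.1% on chromosome 5. The lines differed from each other at 280 loci, 170 higher and 110 lower in line 2. Their log2 fold changes correlated at Pearson's r = 0.882 across loci, against 0.499 in simulated unchanged lines. By rank they agreed less, at Spearman's rho = 0.605, and 71.4% of loci had the same sign in both lines. No rank correlation was taken in the simulation. The covariance was 1.33, against 0.0662 in the simulation. Independent lists of these sizes would share 40.5 higher and 62.2 lower loci, and again part of the excess may come from the shared controls. Leaving out the second or the third wild-type library lowered the count in the mean of both lines to 1712 and 1657, and the count in line 2 to 1632 and 1457. Leaving out the first, the second or the third library of line 1 lowered its own count to 1317, 1354 and 1295.

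Some loci were absent from every library on one side of a comparison and present in every library on the other. Absence was set at below 0.1 CPM and presence at 2 CPM or more, thresholds chosen after seeing the data. In the RGS set, 74 loci were absent from all wild-type libraries and present in all 6 line libraries, and 39 loci showed the reverse. These loci were then read in the amiR set, which had not been used to choose them. Of the 74 loci present in the RGS lines, 59 were present in all 6 amiR line libraries, which carry the other transgene, and 1 was absent from all of them. Of the 39 loci absent from the RGS lines, 32 were absent from all 6 amiR line libraries. In the third wild-type library of the amiR set, 69 of the 74 loci were absent, 0 were present, and 35 of the 39 loci were present, which is the state of the RGS-set wild type. The first and second wild-type libraries of the amiR set had neither state throughout: in both of them 43 of the 74 loci were present and 16 absent, and 25 of the 39 loci were present and 4 absent. The amiR set itself gave 12 loci present only in its lines and 27 present only in its wild type, of which 9 and 21 were also among those of the RGS set. The 4 loci printed by identifier all met this definition in at least 1 set. Such loci often lay next to each other in the order of locus names. Of the 74 loci, 25.7% had a neighbour among tested loci in the same class, against 0.562% on average when the class was permuted (p = 0.001, the smallest that 1000 permutations can give).

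**Figure D3:**
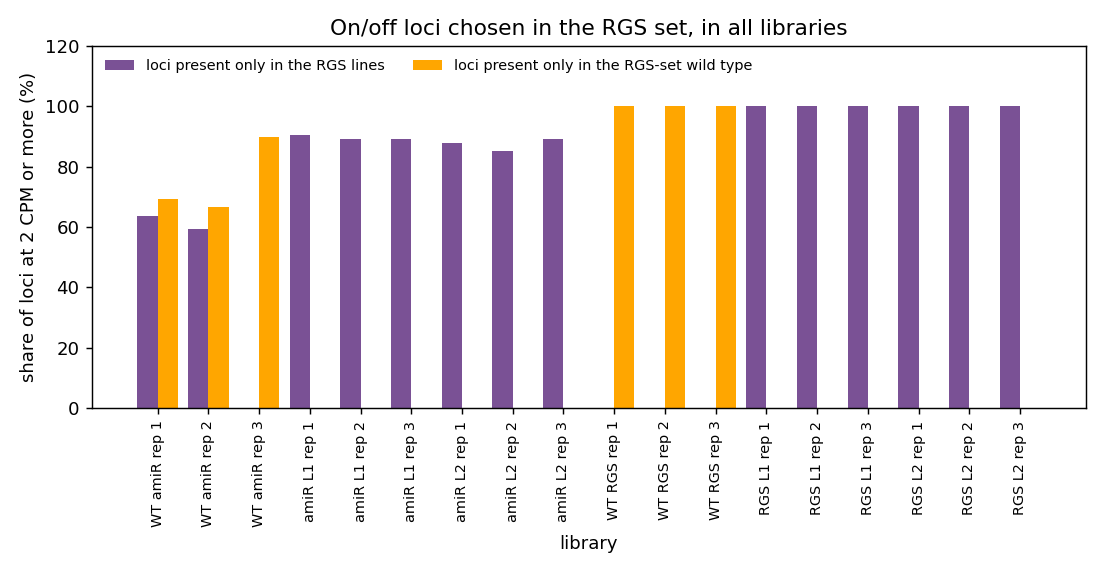
Share of the 74 loci present only in the RGS lines (purple) and of the 39 loci present only in the RGS-set wild type (orange) that reach 2 CPM in each of the 18 libraries (x axis), in percent (y axis). The RGS set shows 0 or 100% because the loci were chosen there. The 6 amiR line libraries hold 85.1 to 90.5% of the 74 loci and 0% of the 39.

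Comparing the sets asked whether the same loci differed in lines with the artificial microRNA and in lines with the RGS transgene. Whether the alpha subunit was lowered was not analysed here. Of 24147 loci tested in both sets, 737 were called in the same direction in the mean of both lines, 290 higher and 447 lower. With limma on log2(TPM + 1) and log2(TPM + 0.1) the shared loci were 361 and 354 higher and 366 and 342 lower. Lists drawn independently would share 56.7 and 127 (Fisher's exact test, p = 3.41e-130 and 1.68e-140). Loci are not independent, so these p-values are too small. Another 130 loci were called in opposite directions, 111 of them higher in the amiR lines and lower in the RGS lines, and 19 the reverse. Independent lists would give 73.6 and 97.6 of these. Over all loci the effects correlated weakly, at Pearson's r = 0.455 and Spearman's rho = 0.103. Of the 737 shared loci, 61 were on/off loci as defined above, and without the on/off loci 676 remained, a count chosen after seeing the data. The correlation of effects depended on the control. Over 22488 loci with a mean above 1 CPM, on the log2(CPM + 0.1) scale, the RGS effect correlated with the amiR effect at r = 0.650 when the third amiR-set wild-type library was the control. It correlated at 0.140 when the first and second were the control, and at 0.318 with all 3.

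**Figure D4:**
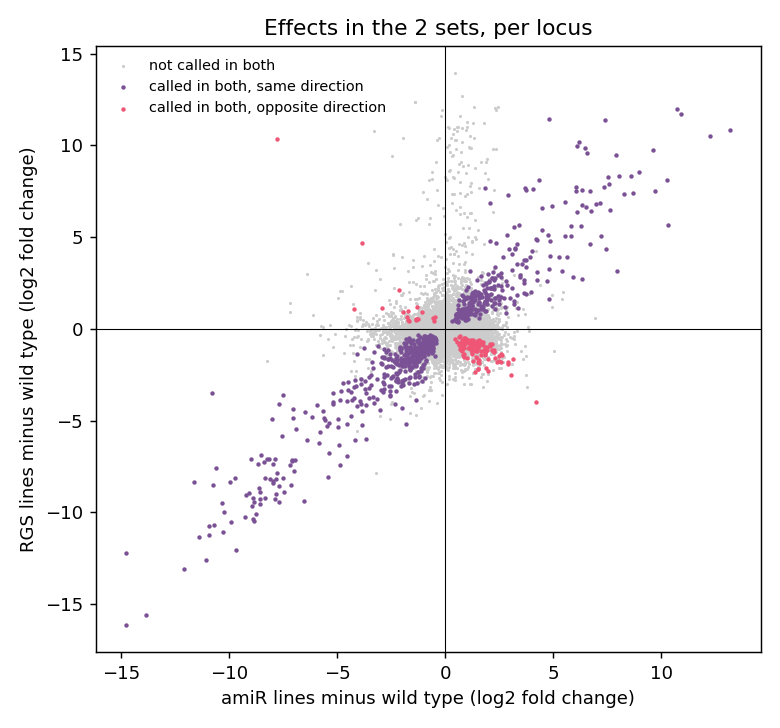
Fitted log2 fold change of the mean of both amiR lines (x axis) and of both RGS lines (y axis) against their own wild type, 1 point per locus tested in both sets, with purple for the 737 loci called in both in the same direction and pink for the 130 called in opposite directions. Loci at 0 counts in a group have fitted values that are no bound on the fold.

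The difference between the effects of the transgenes was tested directly over all 18 libraries. It passed the threshold at 2386 of 26086 loci, with the RGS effect above the amiR effect at 1244 and below it at 1142 (edgeR quasi-likelihood test). That balance turned to 957 above and 1778 below with limma on log2(TPM + 1), and to 812 and 1612 with log2(TPM + 0.1). An adjusted p of 0.01 gave 193 above and 255 below, and leaving out most of the single libraries also turned it, mostly to near even. Among 5155 loci called for either transgene, 1848 (35.8%) had effects that differed, against 9.15% of all 26086 loci. The 5155 were chosen by effects in the same libraries, which raises their share. The count of 2386 also depended on the control libraries of the amiR set. Without the first it was 838, without the second 857 and without the third 9485, and with the third as the only control, chosen after seeing the data, it was 341. Without the second or the third RGS-set wild-type library the count was 1252 and 907. Line libraries moved it as well, to 1556 without the second of amiR line 1, and to 1537 and 1570 without the second and the third of amiR line 2. The wild types of the sets differed from each other at 12973 loci, 49.7% of those tested, 6218 higher and 6755 lower in the RGS-set wild type. That balance moved both ways. Limma gave 8447 higher and 5236 lower on log2(TPM + 1), and 8554 and 5157 on log2(TPM + 0.1), and upper quartile scaling gave 6566 and 6484. A log2 fold change of at least 1 left 2750 higher and 4611 lower, and a fit on the compared groups gave 2594 and 4271. Neither group is labelled as carrying a transgene, and this contrast runs across the library batches.

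The authors' deposited tables of comparisons did not match the labelled groups. Each table gives an effect per transcript as wild type minus line on the natural log scale, and these effects were set against the differences between all pairs of labelled groups. The authors' deposited table for amiR line 1 matched the libraries labelled RGS line 1 minus those labelled amiR line 1, and correlated at r = 0.185 with the pair it names. For amiR line 2, the authors' deposited table matched RGS line 1 minus amiR line 2, with r = 0.141 for its own pair. The authors' deposited table for RGS line 1 matched the RGS-set wild type minus RGS line 2, with r = 0.767 for its own pair. For RGS line 2, the authors' deposited table matched the RGS-set wild type minus the amiR-set wild type, with r = 0.283 for its own pair. In all 4 matches r was at least 0.9998 over 21823 to 21857 transcripts, and the median absolute difference was 0.0001 on the natural log scale after centring. At a q-value below 0.05 the authors' deposited tables list 14349, 14700, 2498 and 7951 transcripts for amiR lines 1 and 2 and RGS lines 1 and 2. Run on the pairs of groups that match, an alternative chosen after seeing the data, the edgeR test called 14629, 15262, 1674 and 6865 loci. Names in the sample labels and in the tables therefore disagree for 3 of the 6 groups. Every comparison, count and direction given above rests on the sample labels. Under the tables' names, the libraries labelled amiR-set wild type would be RGS line 2, and those labelled RGS line 1 would be wild type. The amiR comparisons above would then lack a wild-type control, and the RGS mean would average a wild type with a line. The contrast of the wild types would set a wild type against RGS line 2.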

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

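The tests that weigh explanations in this part were chosen after the results were seen, and the counts over other splits of the libraries were planned.

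The effect differed between the transgenes at 2386 loci by a direct test. Of 100 splits of the libraries within their sets, the real one included, 1 gave as many, and the highest other gave 1071. That other split kept the RGS-set wild type together as controls, but not that of the amiR set. Splits of this kind mostly remove the effect within a set, so they cannot tell whether 2 real effects differ by chance. Lines 1 and 2 differed at 16 loci in the amiR set and at 280 in the RGS set, each by a direct test. The 10 splits of 6 libraries are too few for a share under 0.05. The highest other splits gave 0 loci in both sets.

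For the comparisons of single lines with wild type the 10 splits are too few as well. The real counts of 2260 and 1872 in amiR lines 1 and 2 stand beside highest others of 4 and 0, those of 2052 and 2537 in the RGS lines beside 0 and 0, and the 12973 loci between the wild types beside 1446. The mean of both lines, fitted as 6 against 3 libraries, gave 4117 loci in the amiR set and 2063 in the RGS set, above each of the other splits, of which the highest gave 29 and 172. A chance split is unlikely there, since 1 of 84 splits reached the real count in each set. This share takes the libraries as independent, which the labels do not show. The highest other split in the RGS set parted line 2 from the rest. For the overlaps, 1 of 100 splits gave 1337 loci in both amiR lines, 1342 in both RGS lines and 737 for both transgenes. The highest others were 927, 1124 and 0. The splits with 927 and 1124 loci kept the 3 wild-type libraries as controls and mixed only the lines. Apart from such splits the highest were 9 and 158, so the counts in both lines rest on the wild-type grouping. They do not show by themselves that the lines agree. Splits that break up the wild types leave few calls in either set, so the 0 does not test the overlap between transgenes.

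On/off loci chosen in the RGS set had the state of the RGS lines in most cases in the amiR lines, and that of the RGS-set wild type in the third amiR-set wild-type library, but no single state in the first and second. An effect of the RGS transgene as the whole cause is argued against by the 79.7% of the 74 loci that were also present in all 6 amiR line libraries. On a library batch the amiR-set wild-type libraries disagreed. The third differed in on/off state from the amiR libraries of its own batch at 4.16 times as many loci as from the RGS-set wild type. The first and second went the other way, with 262 to 314 loci against the amiR libraries and 337 to 392 against the RGS-set wild type. This comparison therefore does not decide on a batch. The fragment-length batch that parts the sets is argued against for the on/off loci of the RGS set, which were chosen within that set alone. Within it, the RGS-set wild type differed from the RGS lines at 177 to 230 loci. Across the batches, the amiR lines differed from the RGS lines at 25 to 80. A batch within the RGS set was not tested. A genetic background that differs between the transgenic lines and the labelled wild types is a candidate explanation, and 82.1% of the 39 loci absent from the RGS lines were absent from all 6 amiR libraries too. A response that both transgenes share stays open, since no line carries an empty construct, although under the names in the authors' tables the libraries labelled RGS line 1, which hold the state of the lines, would be wild type.

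The third library of the amiR-set wild type differed from the first and second. A swap with another of the 18 libraries is argued against, since the highest correlation of the first or second with any library of another group was 0.857. A mixture of the material in the other libraries is argued against by 27 loci that were absent from the first and second and present in all 16 others. A different genetic background within this labelled group is a candidate that these data do not test. The third differed in on/off state from the first and second at 340 loci or more, and the highest number within any of the other 5 groups was 39. Any large difference between libraries could give such numbers, and sequence variants were not examined. Which of the 3 libraries matches its label is not shown, no biological explanation that the design names was tested, and a swap with a plant outside the series stays open.

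The authors' tables matched other pairs of labelled groups. Another quantification or model of the same libraries is argued against, as 0 of the 4 tables correlated best with the pair they name. A permutation of 3 group names is a candidate explanation, since one renaming gave correlations of at least 0.9998 in all 4 tables: wild type of the amiR tables for the libraries labelled RGS line 1, RGS line 1 for those labelled RGS line 2, and RGS line 2 for those labelled amiR-set wild type. Whether the sample files or the tables carry the wrong names cannot be told apart. Under the tables' names 1 of 4 comparisons stayed within a fragment-length batch, against 4 under the sample names, but neither arrangement is excluded by the way libraries were prepared.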

How the results depend on the processing

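The alternatives were planned except where stated, the cause of each change was not tested, and each count without 1 library rests on fewer libraries. RLE and upper quartile scaling, no filter, limma on log2(TPM + 1) or log2(TPM + 0.1) and the other table kept all 11 counts within 1.5 times. Only the totals held with limma: as given with the results, the balance of higher and lower loci moved by over 10 percentage points in at least 1 of the limma tests for each of the 4 amiR counts, both transgenes, the difference and the wild types. RLE and upper quartile scaling moved no balance by that much. Depth sets the floors of the printed folds, and its effect on the recovery of small changes was not tested. Counts are given for amiR line 1, amiR line 2, both amiR lines and the mean of both unless named. DESeq2 called 4443, 4065, 2858 and 5828, with 1111 for both transgenes and 3652 for the difference between them. Transcripts gave 999, 849, 625 and 2289, with 1518 for that difference. An adjusted p of 0.01 gave 406, 404, 290 and 905, with 337 for both transgenes, 448 for the difference, and 1044, 1175, 785 and 1366 in the RGS set. Fits on the compared groups gave 375, 521 and 295 for the lines and both lines, 1674 in RGS line 2 and 6865 between the wild types. All 18 libraries in 1 fit gave 4416, 3825, 2798 and 5979. A mean of 50 counts gave 1245 in amiR line 2, 1315 in RGS line 1, 806 in both RGS lines, 1717 in their mean and 419 for both transgenes. A log2 fold change of at least 1 left 2073 in the amiR mean, 1721 in the RGS mean and 7361 between the wild types.

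The replicate block gave 1105, 753, 580 and 2433 and moved no other count by over 1.5 times. Its balance of higher and lower loci was 598 and 507 in amiR line 1, and 673 above and 1074 below for the difference. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0692 to 0.0369 in the amiR set and -0.176 to 0.234 in the RGS set, and 1 of 9 libraries in each set correlated best with its own number.

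Leaving out 1 library gave 430 to 13105 in amiR line 1, 398 to 12503 in amiR line 2, 351 to 10837 in both, 1193 to 13823 in their mean, 1295 to 2571 in RGS line 1, 1457 to 2659 in RGS line 2, 963 to 1577 in both, 1657 to 3350 in their mean, 505 to 1023 for both transgenes, 838 to 9485 for the difference and 10782 to 15669 between the wild types. All 4 amiR maxima came without the third wild-type library. Every other library of the amiR set also lowered at least 3 of these counts by over 1.5 times, and the next highest were 1292, 1241, 735 and 2814.

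Of the alternatives chosen after seeing the data, the third amiR-set wild-type library as the only control gave 3878, 3974 and 2696 for the lines and both, 1193 for both transgenes and 341 for the difference, and assumes that a lone library varies like the other groups. The pairs matching the authors' tables gave 14629, 15262 and 6865 for amiR lines 1 and 2 and RGS line 2. In the mean of both lines, the printed loci stayed on the same side of the threshold and in the same direction in each alternative that tested them. The gene list tests and their alternatives were not run, since no list could be filled.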

Other observations

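The tests in this part were chosen after the results were seen. Loci called in the mean of both lines lay next to each other more often than permuted calls did, in the order of locus names among tested loci. In the RGS set 30.7% of higher loci had a neighbour that was also higher, against 8.19% on average over 1000 permutations, and 25.0% of lower loci had a lower neighbour, against 11.5%. In the amiR set the shares were 18.8% against 11.03% for higher and 29.03% against 18.7% for lower loci. Each p was 0.001, the smallest these permutations can give.

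Besides the on/off loci of the lines, 29 loci were present in the first and second amiR-set wild-type libraries and absent from all 16 others. The first and second differed from each other in on/off state at 4 loci, and from the RGS-set wild type at 337 to 392. The third differed from the RGS-set wild type at 34 to 51 loci, from the amiR lines at 168 to 206 and from the RGS lines at 183 to 244. The 12 line libraries, which hold both transgenes and both batches, differed among themselves at 1 to 80 loci. Between amiR and RGS lines the mean was 48.2 loci, against 15.3 among the amiR lines and 26.5 among the RGS lines.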
